A study of Mus musculus with 8 samples.

How the data were processed

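Total RNA from the small intestine of C57BL/6J Min/+ mice was profiled on 8 single-colour Cy3 microarrays. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, 1 to 3 mice contributed to each array, and feeding is given as 18 months, which is long for these mice and was not checked. The labels place 2 arrays in each of 4 groups of diet and sex. The control diet was the semisynthetic AIN-93G formula. Per the labels, 66.4% of the fat of the Western-type diet was milk fat and 33.6% came from rapeseed and sunflower oil. Arrays are named here by group and number, such as Control male 1. The labels do not say that the 2 arrays of a group hold RNA of different mice, so p-values measure only the spread between these arrays, which may be partly technical.

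Each deposited file was the output of 1 Agilent array (design 026655) from Feature Extraction 10.7.3.1, per the file headers. The deposited values used here were the processed signal of each spot, an intensity on a linear scale from which the scanner software had already subtracted background, per the file headers. No normalization between arrays was recorded in the files. Slide 1 held replicate 1 of all 4 groups, slide 2 held Western male 2, and slide 3 held Control male 2, Control female 2 and Western female 2. Slides 1 and 2 were scanned on day 1 and slide 3 on day 2.

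The 1377 control spots and the spots the scanner software had marked as outliers (94 to 216 per array) were left out, and the spots of each of 399 repeated probes were averaged. No spot was marked as saturated. Values were log2 of the processed signal minus the 75th percentile of the array. Probe accessions were named through a RefSeq table (assembly GRCm38.p6), without versions. The headers name an older mouse build (mm9), so no coordinates are given. Of 39429 probes, 26412 received a symbol (20017 symbols) and 13017 kept the name in the file. Probes well above background on at least 2 arrays were kept (25737). For each gene the probe with the highest mean was tested, which gave 21307 genes, 14826 of them with a symbol. Other probes of Anxa8, Col14a1, Cxcl9, Cyp4a31, H2-Ob, Hmox1, Kdr, Nlrc5 and Tnfrsf19 gave different values.

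Differences were fitted with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) as 4 group means over all 8 arrays, with moderated variances (4 residual and 2.01 prior degrees of freedom). The contrasts were Western minus control diet averaged over the sexes, the same within males and within females, the difference between these (females minus males), and female minus male averaged over the diets. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of log2 differences are standard errors (SE). Where a gene was not well above background on any array of the lower side, a bound is printed. It is the mean of the brighter side minus the mean over the dimmer side's arrays of the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where that bound was under 1, and none for differences between the sexes in the diet effect of such genes.

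The 43 gene lists covered lipid and energy metabolism, growth signalling, epithelial cell types, immunity, contaminating tissues, stress, and sex. They were tested with limma's camera at a preset inter-gene correlation of 0.01 over the genes measured on every array (21290), with adjustment over the lists. Camera sets a list against the other genes, and the median of all genes was -0.058 for diet, -0.009 in males, -0.109 in females, -0.136 for the difference and 0.075 for sex. Camera with an estimated correlation and fry served as checks. For lists, log2 values are means over the measured members. Counts of members are given adjusted over all genes tested and adjusted over the list alone. The groups, contrasts, lists, threshold and most alternatives were fixed before the data were examined. Exact two-sided permutation tests reassigned the 8 arrays to 2 groups of 4, for the 43 list means and Pdk4 in each of the diet and sex comparisons.

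The rule for named genes was fixed at the same time. It took the 5 genes with a symbol and the smallest p in each direction where too few passed the threshold (for the diet effect with the same sign in both sexes), up to 4 members of any list past its threshold, up to 3 members of other lists on subjects that the series title names, Pdk4, and the Y-linked genes and Xist. Which of these genes the text prints was decided with the values in view, and a gene that the rule named is not reported here. In every comparison the smallest p belonged to a probe without a symbol. Sis for the diet effect, S100g for males and Ddx3y outside the sex comparison, as well as Krt6a and Gm5476, lay outside the rule in those comparisons and were chosen after their values were seen. The haemoglobin, serum amyloid A, glutathione transferase, class I and class II, and mast cell protease genes have close paralogs whose transcripts can hybridise to each other's probes.

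The procedure was tested on data simulated with the moderated variance of each gene, not its own spread (21290 genes, 200 changed). For the diet effect, 0% of genes changed by 1 log2 unit were recovered, 73.5% at 2 and 98.5% at 4, with 0, 7 and 9 false calls. Within males the shares were 0%, 15.5% and 89.5%, and within females 0%, 34.0% and 90.0%. Of 10 lists of 40 genes shifted by 0.3 for diet, 10 were called, and of 10 without a shift, 0. The simulations held no slide or scan day differences or inter-gene correlation, so they do not check the list calls.

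Alternatives covered background correction, scaling, the filter on dim probes, outlier spots, the choice of probe, blocks for replicate number, slide and scan day, variance model, array weights, an additive model, slide 1 alone, thresholds, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.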

Results

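Gene expression was measured in the small intestine of ApcMin/+ mice, which carry a truncating mutation in the Apc tumour suppressor gene and develop intestinal adenomas. The 4 groups of 2 arrays were males and females on a control diet or a Western-type diet rich in milk fat. The 75th percentile of the signal lay between 486 (Control female 2) and 902 (Western male 1). On 7 arrays 55.1% to 61.9% of probes were well above background, against 75.6% on Control female 2. Pairwise correlations between arrays over genes lay between 0.942 and 0.990. The first principal component (43.4% of the variance) set Control female 2 (score -146.4) apart from the other arrays, whose scores ranged from -1.6 to 33.2.

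Y-linked transcripts served as a check of the labels. Ddx3y, which encodes an RNA helicase, measured between -1.04 and -0.67 on the 4 male arrays, in log2 relative to the 75th percentile. It measured -6.91, -7.56 and -7.47 on Control female 2, Western female 1 and Western female 2, where it was not well above background, and -0.46 on the library labelled Control female 1. Eif2s3y, a translation initiation factor subunit, measured 1.75 to 2.45 on the male arrays and 1.90 on the library labelled Control female 1. On the other 3 female arrays it measured -6.69, -5.58 and -7.28. Uty, a histone demethylase, measured -3.39 to -2.72 on the male arrays, -2.71 on the library labelled Control female 1 and -5.16 to -7.55 on the other female arrays. Xist probes were well above background on 0 arrays and Kdm5d probes on 1, so neither could serve as a check. The library labelled Control female 1 therefore carried Y-linked transcripts at the level of the male arrays. It was kept in the group its label gives, and every direction that uses the Control female group rests partly on it.

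**Figure D1:**
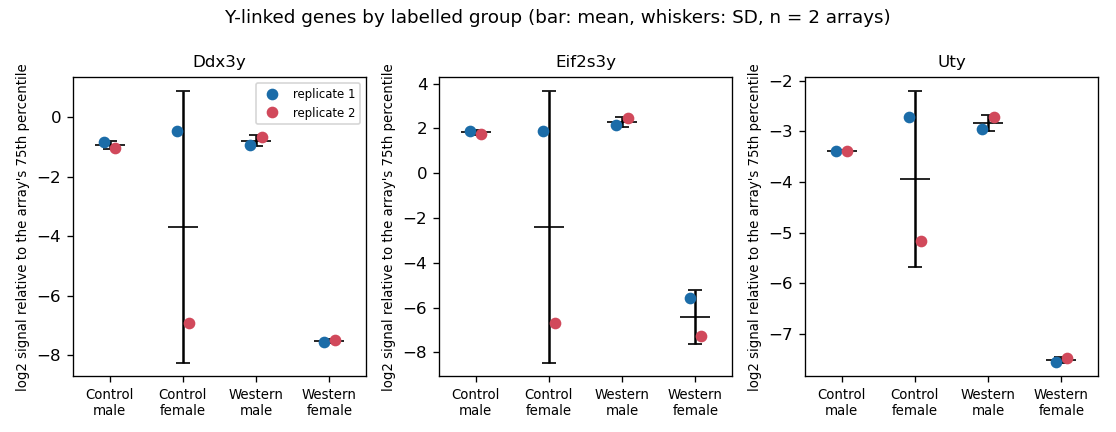
Log2 signal relative to the array's 75th percentile of the Y-linked genes Ddx3y, Eif2s3y and Uty on each array, by labelled group, with bars at the mean and whiskers for the SD (n = 2). The library labelled Control female replicate 1 lies with the male arrays.

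The first comparison in the series design text set the Western-type diet against the control diet. Pdk4, which the series title names, encodes a kinase that inhibits pyruvate dehydrogenase. It was 9.41-fold higher on the Western diet (log2 3.23 ± 0.49 SE, n = 4 arrays per diet). Its log2 signal was -2.68 ± 0.93 on the control and 0.56 ± 0.79 on the Western diet (SD, n = 4). Each Western array lay above each control array. Its adjusted p was 0.407 by limma, and an exact permutation test gave p = 0.0286, the smallest that 70 assignments allow (adjusted over the lists and Pdk4, 0.838). The genes of fatty acid oxidation under PPAR transcription factors, Pdk4 included, were higher as a list (mean 0.293, median 0.177, 34 of 45 members higher, camera adjusted p = 1.13e-07, 0.786 with an estimated correlation). The sucrose-digesting sucrase-isomaltase (Sis) was 2.09-fold lower (log2 -1.06 ± 0.16 SE, adjusted p = 0.407). By limma, 0 of 21307 genes passed an adjusted p of 0.05 (smallest 0.125), while 910 had an unadjusted p under 0.05 (138 higher, 772 lower), where chance alone gives 1065. Of these 910 genes 15.2% were higher, against 58.7% of 745 after quantile normalization, which shifted the median of all genes from -0.058 to 0.041. Without Control female 2, 1 gene passed, the Y-linked Ddx3y (-3.46, adjusted p = 0.0456; -1.85, adjusted p = 0.995, with all 8 arrays). It was well above background on the male arrays and on the library labelled Control female 1, then alone in its group.

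**Figure D2:**
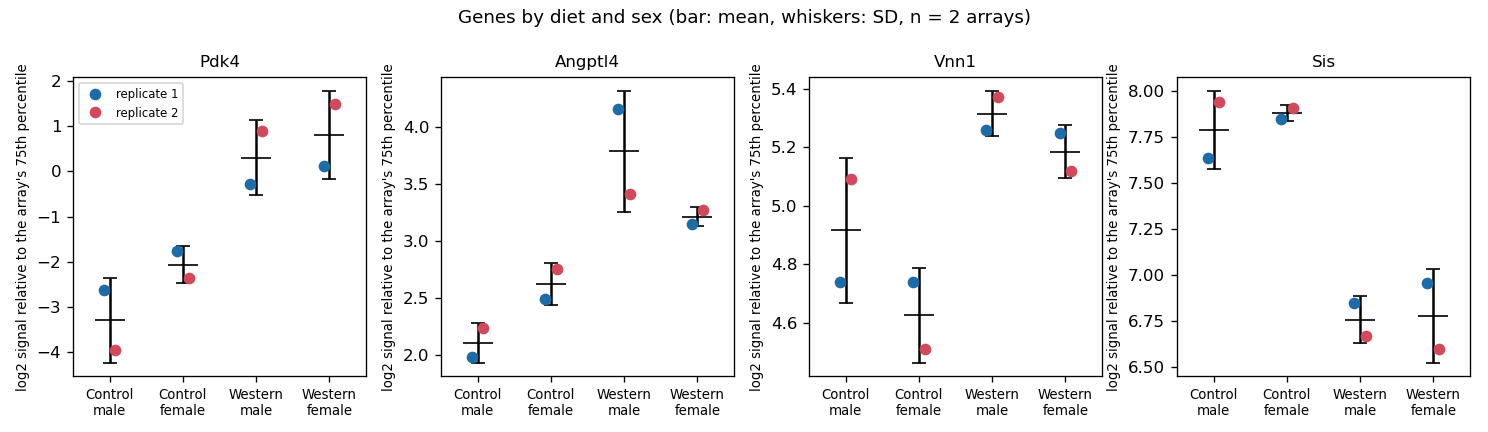
Log2 signal relative to the array's 75th percentile of Pdk4, Angptl4, Vnn1 and Sis on each array, by group, with bars at the mean and whiskers for the SD (n = 2).

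Among 43 lists camera called 8 for the diet, all higher on the Western diet, and 0 remained past the threshold with an estimated correlation or by fry (smallest adjusted p = 0.786 and 0.988). By exact permutation the 8 lists, in the order below, had p = 0.114, 0.314, 0.0857, 0.171, 0.486, 0.429, 0.486 and 0.0857 (adjusted 0.838 or 0.951). Whichever library was left out, 4 of the 8 calls held, for fatty acid oxidation, xenobiotic metabolism, oxidative stress and erythrocytes. Called lists numbered 14 without Western male 2 and 14 without Western female 1. Of the 45 fatty acid oxidation members, 0 passed adjusted over all genes and 2 adjusted over the list alone, Pdk4 and Angptl4. Angptl4, a secreted inhibitor of lipoprotein lipase, was 2.20-fold higher (log2 1.14 ± 0.21 SE, adjusted p = 0.650). The pantetheinase gene Vnn1 was 1.39-fold higher (log2 0.48 ± 0.16 SE) and the acyl-CoA dehydrogenase gene Acadl 1.85-fold higher (log2 0.88 ± 0.37 SE). That count of 2 became 0 without Control male 2, Control female 2, Western male 1 or Western female 2 and 1 without Control male 1, Western male 2 or Western female 1. The list mean was 0.168 without Control female 2, 0.283 with scan day as a block (below, blocked by day), 0.131 within slide 1 and 0.503 within slide 3, where females alone could be compared. Within these batches Pdk4 differed by 3.19 blocked by day, 2.12 within slide 1 and 3.85 within slide 3, and Angptl4 by 1.19, 1.42 and 0.52.

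The xenobiotic metabolism list, enzymes and transporters for foreign compounds, rose by 0.304 (23 of 33 members higher, adjusted p = 5.39e-05), with 0 members past either adjustment. The cytochrome P450 genes Cyp2c55 and Cyp2c66 were 2.95-fold (log2 1.56 ± 0.48 SE) and 1.67-fold (log2 0.74 ± 0.29 SE) higher, and the glutathione transferase gene Gstm3 was 2.38-fold higher (log2 1.25 ± 0.45 SE). Ahrr, the repressor of the aryl hydrocarbon receptor, was 1.54-fold lower (log2 -0.62 ± 0.21 SE). The list mean depended on single libraries, at 0.470 without the library labelled Control female 1, 0.135 without Control female 2, 0.544 without Western male 1 and 0.0930 without Western male 2. It was 0.257 blocked by day, -0.127 within slide 1 and 0.510 within slide 3.

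The list of oxidative stress genes under the transcription factor Nrf2 rose by 0.196 (19 of 23 members higher, adjusted p = 5.66e-05), with 0 members past either adjustment. The glutathione reductase gene Gsr was 1.43-fold higher (log2 0.52 ± 0.20 SE) and Gclm, a subunit of the enzyme that starts glutathione synthesis, 1.36-fold higher (log2 0.44 ± 0.20 SE). The list mean was 0.204 blocked by day, 0.135 within slide 1 and 0.233 within slide 3, and without Control male 2 the count adjusted over the list alone was 1. Class I antigen presentation genes rose by 0.145 (18 of 21 members higher, adjusted p = 0.000199), with 0 members past either adjustment. The immunoproteasome subunit genes Psmb8 and Psmb9 were 1.31-fold (log2 0.39 ± 0.18 SE) and 1.22-fold (log2 0.29 ± 0.15 SE) higher. The class I call was lost without Control male 1 (0.119, adjusted p = 0.0564), the mean was 0.0890 without Western female 1, and it was 0.147 blocked by day, 0.301 within slide 1 and -0.1 within slide 3.

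The interferon response list rose by 0.151 (27 of 40 members higher, adjusted p = 0.000208), and 0 members passed either adjustment. Irf7, a transcription factor of the interferon response, was 1.28-fold higher (log2 0.35 ± 0.14 SE) and the antiviral gene Rsad2 1.55-fold higher (log2 0.63 ± 0.32 SE; -0.22 within slide 3). The call was lost without the library labelled Control female 1 (-0.0200, adjusted p = 0.111) and without Western male 1 (0.0340, adjusted p = 0.205), and the mean was 0.308 without Control female 2, 0.268 without Western male 2 and 0.0910 without Western female 1. It was 0.181 blocked by day, 0.477 within slide 1 and -0.455 within slide 3. The granulocyte and mast cell list rose by 0.363 (11 of 20 members higher, median 0.0470, adjusted p = 0.00680), with 0 members past either adjustment. The members with the smallest p were mast cell genes, but another, Tpsb2, had -0.30 and -0.27 on 2 probes. Fcer1a, a chain of the IgE receptor, was at least 1.44-fold higher (2 arrays well above background), the carboxypeptidase gene Cpa3 at least 1.63-fold higher (3 arrays), and the protease genes Mcpt1 and Mcpt4 were 2.40-fold (log2 1.26 ± 0.53 SE) and 2.34-fold (log2 1.22 ± 0.52 SE) higher. Mcpt1 and Mcpt4 had 1.92 and 1.90 within slide 1 and turned to -0.82 and -0.90 within slide 3, where Fcer1a was not well above background. The call was lost without Control male 2 (0.197, adjusted p = 0.0960), the library labelled Control female 1 (0.0350, adjusted p = 0.152) or Western male 1 (0.111, adjusted p = 0.288), and the mean was 0.713 without Control female 2. It was 0.430 blocked by day, 0.648 within slide 1 and -0.467 within slide 3.

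Markers of Wnt signalling and stem cells rose by 0.130 (17 of 28 members higher, adjusted p = 0.0274), with 0 members past either adjustment. Clu, which encodes clusterin, was 2.38-fold higher (log2 1.25 ± 0.54 SE), and Rnf43, a ubiquitin ligase that restrains Wnt receptors, was 1.24-fold higher (log2 0.31 ± 0.19 SE). The call was lost without Control male 2 (0.0620), the library labelled Control female 1 (0.0370), Control female 2 (0.229), Western male 1 (0.0220) or Western female 2 (0.0980), and the mean was 0.197 without Control male 1, 0.238 without Western male 2 and 0.207 without Western female 1. It was 0.164 blocked by day, 0.185 within slide 1 and 0.0540 within slide 3. Transcripts of red blood cells rose by 1.191 as a list (7 of 7 members higher, adjusted p = 5.18e-08), and 0 members passed adjusted over all genes and 5 adjusted over the list alone. The globin genes Hba-a2 and Hbb-bt were 2.61-fold (log2 1.38 ± 0.33 SE) and 3.58-fold (log2 1.84 ± 0.45 SE) higher. The erythrocyte list mean was 1.268 blocked by day, 1.829 within slide 1 and 1.673 within slide 3, and the count of 5 became 0 without Control male 1, the library labelled Control female 1, Western female 1 or Western female 2.

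**Figure D3:**
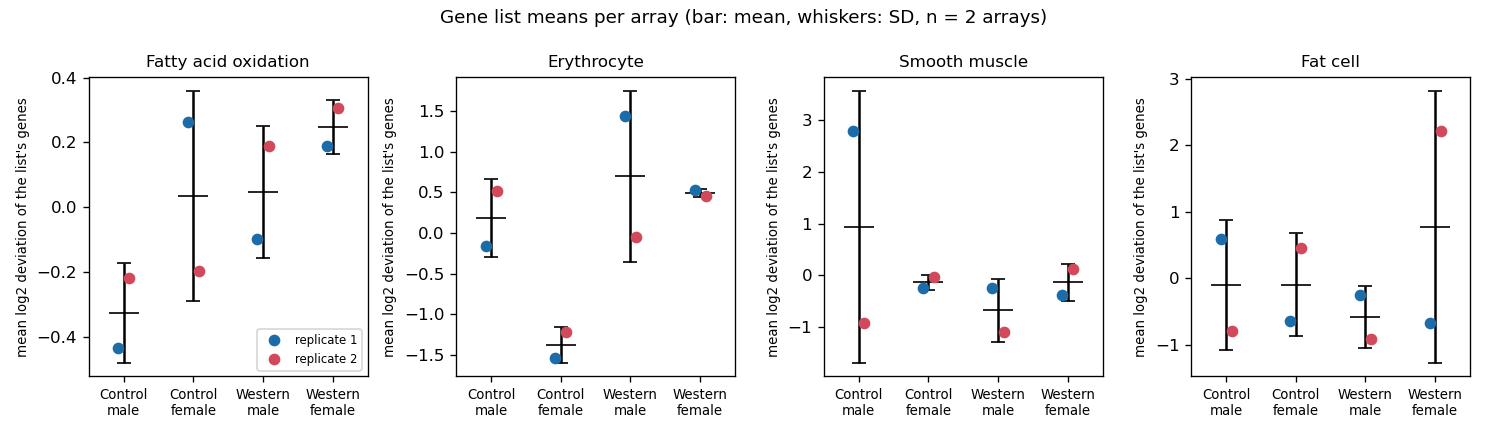
Mean log2 signal of the members of the fatty acid oxidation, erythrocyte, smooth muscle and fat cell lists on each array, by group. Values are relative to the mean of the 8 arrays.

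The series title names energy metabolism, and those lists did not pass for diet. Oxidative phosphorylation had a mean of 0.0110 and a median of -0.00300 (36 of 76 members higher, adjusted p = 0.0947), the TCA cycle a mean of 0.0230 and a median of -0.00900 (11 of 24 higher, adjusted p = 0.613) and glycolysis and glucose transport a mean of -0.157 (10 of 33 higher, adjusted p = 0.613). Single genes of glucose handling differed in opposite directions, without passing over all genes. The glucose transporter genes Slc2a2 and Slc5a1 were 2.87-fold (log2 -1.52 ± 0.46 SE) and 1.89-fold (log2 -0.92 ± 0.32 SE) lower on the Western diet. G6pc and Pck1, which encode enzymes of gluconeogenesis, were 2.21-fold (log2 1.14 ± 0.38 SE) and 2.58-fold (log2 1.36 ± 0.61 SE) higher. The ATP synthase gene Atp5g3 was 1.18-fold higher (log2 0.24 ± 0.19 SE; -0.15 within slide 3). Among other lipid lists, fat absorption had a mean of 0.0540 (adjusted p = 0.219), fatty acid synthesis 0.203 with a median of 0.00500 (10 of 19 higher, adjusted p = 0.369) and cholesterol synthesis -0.173 with 22 of 25 members lower (adjusted p = 0.205).

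Growth signalling, also named in the title, showed no list past the threshold. The Erk and MAP kinase list had a mean of -0.159 (24 of 35 members lower, adjusted p = 0.619), the PI3K, Akt and Foxo list 0.0140 (adjusted p = 0.0947) and the mTor list -0.0450 with a median of 0.0170 and an upward test direction (adjusted p = 0.244). Phlda1, a target of Erk signalling, was 1.61-fold lower (log2 -0.69 ± 0.20 SE) and Fos, an immediate early transcription factor, 1.64-fold lower (log2 -0.71 ± 0.29 SE). Klf15, a transcription factor of fasting metabolism, was 1.95-fold higher (log2 0.96 ± 0.36 SE). Sesn2, an inhibitor of mTor complex 1, had a log2 difference of -0.25 ± 0.14 SE, and Rptor, a subunit of that complex, 0.22 ± 0.18 SE. The proliferation list had a mean of -0.119 (27 of 34 members lower, adjusted p = 0.613).

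Among immune lists that did not pass for diet, T cells had a mean of -0.0830 (tested upward, adjusted p = 0.613), B and plasma cells 0.0270 (adjusted p = 0.482), macrophages and dendritic cells -0.0140 with a median of 0.0740 and an upward test direction (adjusted p = 0.205), class II antigen presentation -0.111 (tested upward, adjusted p = 0.682), and cytokines and inflammation -0.196 (adjusted p = 0.642). Pigr, the receptor that carries IgA across the epithelium, was 1.64-fold lower (log2 -0.71 ± 0.28 SE), as were Il22, a cytokine that acts on epithelium (1.71-fold, log2 -0.77 ± 0.35 SE), and the chemokine gene Ccl19 (1.31-fold, log2 -0.39 ± 0.16 SE). The macrophage lectin gene Clec10a had a log2 difference of 0.57 ± 0.24 SE, and -0.03 with another background correction (normexp). Ctss, a protease of antigen processing, had 0.28 ± 0.15 SE, and the antimicrobial lectin gene Reg3a 0.22 ± 0.19 SE (-0.11 within slide 3).

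Epithelial lists did not pass for diet either. The enterocyte list had a mean of -0.114 (20 of 30 members lower, adjusted p = 0.613), with 1 member, Sis, past adjusted over the list alone. Sis differed by -1.06 blocked by day, -0.84 within slide 1 and -1.32 within slide 3. The means were 0.0590 for proximal intestine (adjusted p = 0.433), 0.1 for bile acid and distal intestine (adjusted p = 0.108), -0.0550 for Paneth cells (tested upward, adjusted p = 0.697), -0.113 for goblet cells (adjusted p = 0.201), -0.0500 for enteroendocrine cells (tested upward, adjusted p = 0.763) and 0.0490 for tuft cells (adjusted p = 0.219). Adenoma-associated genes had a mean of 0.171 (median 0.0490, 14 of 27 higher, adjusted p = 0.0607). Vitamin D and calcium genes had a mean of 0.0250 and a median of -0.277 (adjusted p = 0.431), folate metabolism -0.122 (adjusted p = 0.604), endoplasmic reticulum (ER) stress -0.0390 (tested upward, adjusted p = 0.573), immediate early and heat shock genes -0.143 (adjusted p = 0.613) and the circadian clock -0.112 with a median of 0.00900 and an upward test direction (adjusted p = 0.697).

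Markers of other tissues varied between libraries. Smooth muscle had a diet mean of -0.802 (adjusted p = 0.0874), neurons and glia -0.829 (adjusted p = 0.0947), fibroblasts -0.243 (tested upward, adjusted p = 0.969), fat cells 0.195 with a median of -0.0390 (adjusted p = 0.443), endothelium 0.0720 (adjusted p = 0.449), pancreatic acinar cells -0.215 (adjusted p = 0.462) and the sex chromosome list -1.710 (adjusted p = 0.0947). Blocked by day, smooth muscle (-1.053, adjusted p = 0.00508, 0.810 with an estimated correlation; 0.156 within slide 3) and the sex chromosome list (-2.247, adjusted p = 0.0158, 0.741 with an estimated correlation) were called lower. Control male 1 had a smooth muscle mean of 2.80, relative to the mean of all arrays, against -1.10 to 0.122 on the others, and a fibroblast mean of 1.74. Western female 2 had a fat cell mean of 2.22. The erythrocyte mean was -1.53 and -1.22 on the Control female arrays and 1.44 on Western male 1.

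Of genes with a small p for diet, Spats1, D6Ertd527e, Kng2 and Foxj1, a transcription factor of ciliated cells, differed by -1.71, -1.68, -1.80 and -1.81 (adjusted p = 0.278 each). These 4 were well above background only on the Control female arrays, and no bound above 1 could be given. With normexp, which adds a constant to every signal, they differed by -0.44, -0.33, -0.50 and -0.47, Ahrr by -0.34, Fcer1a by 0.17 and Cpa3 by 0.28. Rasgrp1, an activator of Ras in lymphocytes, was 1.89-fold higher (log2 0.92 ± 0.17 SE, adjusted p = 0.650; 0.41 with normexp), and Renbp, which encodes renin-binding protein, 5.51-fold higher (log2 2.46 ± 0.57 SE, adjusted p = 0.995).

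In males (2 arrays per diet) Pdk4 was 12.1-fold higher on the Western diet (log2 3.6 ± 0.69 SE) and Angptl4 3.20-fold higher (log2 1.68 ± 0.30 SE). The keratin gene Krt14 was 6.85-fold higher (log2 2.78 ± 0.28 SE, adjusted p = 0.691), 1.76 with normexp, 2.74 blocked by day and 2.43 within slide 1. S100g, which encodes the calcium-binding protein calbindin-D9k, was 6.39-fold higher (log2 2.68 ± 0.53 SE), and Sis was 2.04-fold lower (log2 -1.03 ± 0.23 SE). By limma, 0 genes passed (smallest adjusted p = 0.691), and 277 had an unadjusted p under 0.05 (124 higher, 153 lower). Adjusted p was 1.00 for the other genes of this comparison. The annexin gene Anxa8 was 6.45-fold higher (log2 2.69 ± 0.38 SE), although another probe of it gave a different value for diet (-0.0800 against 0.990). Fcer1a was at least 3.05-fold higher, Wnt4, a Wnt ligand, at least 2.62-fold lower, Eno4 at least 1.20-fold lower and Septin14 at least 1.11-fold lower, measured on 2, 6, 4 and 2 arrays. With normexp Fcer1a had 0.53, Wnt4 -0.59, Eno4 -0.42 and Septin14 -0.54.

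In males camera called 14 lists, 10 higher and 4 lower on the Western diet, and 0 with an estimated correlation (adjusted p = 0.803 for each of the 14) or by fry (smallest 0.972). Of the 14 calls, 0 were kept whichever library was left out, and 9 were lost without Control male 1, 3 without Control male 2, 5 without Western male 1 and 6 without Western male 2. Oxidative phosphorylation rose by 0.206 (74 of 76 members higher, camera adjusted p = 1.13e-09), with Ndufs5 and Atp5g3, subunits of complex I and ATP synthase, at 0.43 ± 0.28 SE and 0.42 ± 0.27 SE. Its mean was 0.357 without Western male 1 and 0.0560 without Western male 2, where the call was lost. Its genes correlated (estimated 0.659), so member counts here and below are not independent. The median bright gene (log2 over 2) deviated by -0.16 and -0.01 on the Control and -0.09 and 0.12 on the Western male arrays. This shift was not removed. Fatty acid oxidation rose by 0.373 (35 of 45 higher, 2 past adjusted over the list alone, adjusted p = 3.10e-06), with the call lost without Control male 1 (0.263) and a mean of 0.232 without Western male 2. Xenobiotic metabolism rose by 0.515 (26 of 33 higher, adjusted p = 7.45e-06), with Gstm3 3.5-fold higher (log2 1.81 ± 0.64 SE) and Ahrr 2.29-fold lower (log2 -1.20 ± 0.29 SE; -0.61 with normexp). Its call was lost without Control male 1 (0.497) or Western male 2 (0.0920), and it had 0.976 without Western male 1. The Nrf2 list rose by 0.294 (adjusted p = 2.57e-05), with the glutathione peroxidase gene Gpx2 1.95-fold higher (log2 0.96 ± 0.40 SE), and lost its call without Control male 1 (0.188).

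Class I genes rose by 0.203 in males (19 of 21 higher, adjusted p = 0.000317; lost without Control male 1, 0.151, or Western male 1, 0.127) and interferon response genes by 0.295 (28 of 40 higher, adjusted p = 0.000135; lost without Western male 1, 0.0210, and 0.529 without Western male 2). The granulocyte list rose by 0.616 (median 0.140, 11 of 20 higher, adjusted p = 0.00604), with Fcer1a past adjusted over the list alone, Cpa3 at least 2.56-fold higher (0.53 with normexp) and Mcpt1 4.40-fold higher (log2 2.14 ± 0.75 SE). It lost its call without Control male 2 (0.285) or Western male 1 (0.191) and had 0.935 without Control male 1. Bile acid genes (0.174, adjusted p = 0.0343), tuft cell genes (0.318, adjusted p = 0.0258) and erythrocyte genes (0.515, adjusted p = 0.0258) were called higher. The first of these had means of 0.270 without Control male 1 and -0.0230 without Western male 2, the second 0.387 without Control male 1, 0.249 without Control male 2 and -0.214 without Western male 2, and the third 0.177 without Control male 1 and -0.228 without Western male 1, where each call was lost. Without Western male 1 the first had 0.372 and the second 0.850, without Control male 2 the first had 0.0790 and the third 0.854, and without Western male 2 the third had 1.258. S100g passed adjusted over the vitamin D and calcium list alone, while that list did not pass (adjusted p = 0.746).

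Smooth muscle genes fell by 1.61 in males (0 of 17 members higher, adjusted p = 6.88e-07) and fibroblast genes by 0.768 (4 of 30 higher, adjusted p = 0.000177). Without Control male 1 the means were 0.285 and 0.349 and the calls were lost. The fibroblast call was also lost without Western male 2 (-0.318), and its mean was -1.864 without Control male 2 and -1.233 without Western male 1. Smooth muscle had -3.468 without Control male 2. The contractile genes Myh11 and Cnn1 differed by -3.04 ± 1.90 SE and -2.64 ± 1.64 SE, and Myh11, measured on 3 arrays, by -1.90 with normexp and 0.00 without Control male 1. Timp1, an inhibitor of matrix proteases, went against its list and was at least 2.89-fold higher (0.52 with normexp). Macrophage genes fell by 0.299 (3 of 29 higher, adjusted p = 0.000175), with the cytokine receptor gene Flt3 at -0.79 ± 0.36 SE (-0.42 with normexp), and lost the call without Western male 2 (-0.140), with -0.459 without Western male 1. Immediate early genes fell by 0.299 (adjusted p = 0.00407) and lost the call without Control male 2 (-0.221) or Western male 1 (-0.269).

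Blocked by day, the male means were 0.352 for fatty acid oxidation, 0.155 for oxidative phosphorylation, 0.420 for xenobiotic metabolism, 0.311 for Nrf2, 0.208 for class I, 0.355 for interferon response, 0.75 for granulocytes, 0.396 for tuft cells, 0.668 for erythrocytes, -2.111 for smooth muscle, -0.850 for fibroblasts, -0.181 for macrophages and -0.174 for immediate early genes, and the bile acid call was lost (0.129, adjusted p = 0.186). Proliferation (-0.212, adjusted p = 0.0176), goblet cell (-0.0860, adjusted p = 0.0196) and B and plasma cell genes (-0.338, adjusted p = 0.0418; 0.1 within slide 1) were called lower with this block, with adjusted p = 0.893 each with an estimated correlation. Within slide 1 the first 13 lists had 0.338, 0.0950, 0.0680, 0.308, 0.330, 0.486, 0.608, -0.283, 1.596, -3.037, -1.414, -0.191 and -0.251, and bile acid genes -0.119.

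In females the Western diet arrays were set against the Control female libraries, of which 1 carried Y-linked transcripts and the other had raised dim signals. The globin genes Hbb-bt and Hba-a2 were 8.08-fold (log2 3.01 ± 0.64 SE, adjusted p = 0.806) and 4.67-fold (log2 2.22 ± 0.46 SE, adjusted p = 0.749) higher on the Western diet. Pdk4 was 7.32-fold higher (log2 2.87 ± 0.69 SE, adjusted p = 0.940) and Rasgrp1 2.17-fold higher (log2 1.12 ± 0.24 SE, adjusted p = 0.810; 0.41 with normexp). Slc1a3, a glutamate transporter, was at least 2.39-fold higher (adjusted p = 0.883, 2 arrays; 0.13 with normexp). By limma, 0 genes passed (smallest adjusted p = 0.0855), and 1086 had an unadjusted p under 0.05 (128 higher, 958 lower). Without the library labelled Control female 1, only Control female 2 was left as control. With the genes chosen on 8 arrays kept, the dim genes Spats1, D6Ertd527e, Kng2 and Foxj1 then differed by -3.19, -3.23, -3.16 and -3.70. An effect of diet on such genes cannot be told apart from that array's raised signals. Without Control female 2, 2 genes passed, Ddx3y (at least 34.0-fold lower, adjusted p = 0.00985; at least 3.64-fold with all arrays) and Uty (at least 7.15-fold lower, adjusted p = 0.0313), measured in females on the library labelled Control female 1 alone.

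Among genes with a symbol, the lowest p in females belonged to some well above background only on the Control female arrays. Since 1 of these had raised dim signals, the bounds set no minimum diet effect. By these bounds Spats1 was 2.03-fold lower on the Western diet, D6Ertd527e 1.87-fold, Kng2 2.19-fold, Foxj1 2.17-fold and Ric3, a chaperone of acetylcholine receptors, 1.82-fold (adjusted p = 0.0956 each). With normexp they differed by -0.64, -0.53, -0.78, -0.71 and -0.68. Uty was at least 3.06-fold lower (adjusted p = 0.749; -0.88 with normexp). Vnn1 was 1.47-fold higher (log2 0.56 ± 0.22 SE), Igf1r, the receptor of insulin-like growth factor, 1.63-fold higher (log2 0.71 ± 0.26 SE) and Pigr 2.24-fold lower (log2 -1.16 ± 0.40 SE), each with an adjusted p of 0.954.

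In females camera called 14 lists, 13 of them higher on the Western diet, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.615 and 0.975). Of these calls 2 were kept whichever library was left out, and 9 were lost without the library labelled Control female 1, 6 without Control female 2, 5 without Western female 1 and 6 without Western female 2. The first of the 2 was erythrocytes, which rose by 1.867 (7 of 7 higher, 5 past adjusted over the list alone, camera adjusted p = 3.14e-09, 0.615 with an estimated correlation). Its mean was 2.061 within slide 1 and 1.673 within slide 3. The other was macrophages, which rose by 0.272 (21 of 29 higher, adjusted p = 1.02e-06, 0.839 with an estimated correlation). It had 0.235 within slide 1 and 0.308 within slide 3. Its mean was 0.0860 without the library labelled Control female 1, 0.448 without Control female 2, 0.494 without Western female 1 and 0.0490 without Western female 2. Clec10a was 2.17-fold higher (log2 1.12 ± 0.34 SE; 0.08 with normexp) and Ly86, a partner of a Toll-like receptor homologue, 1.76-fold higher (log2 0.81 ± 0.27 SE).

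The other female calls depended on single libraries, and the adjusted p with an estimated correlation was 0.839 unless given. Fatty acid oxidation rose by 0.214 (32 of 45 higher, adjusted p = 0.000157), against -0.0260 without Control female 2, where the call was lost, and 0.443 without the library labelled Control female 1. Fat cell genes rose by 0.869 (11 of 16 higher, adjusted p = 0.0148), against -0.577 without Western female 2 and 0.319 without the library labelled Control female 1, where the call was lost. The fat cell genes Fabp4 and Cfd differed by 3.09 ± 1.77 SE and 3.48 ± 2.41 SE, with Cfd at 3.29 on Western female 2 and -4.33 on Western female 1. Fibroblast genes (0.282, adjusted p = 0.00642) and endothelial genes (0.413, adjusted p = 0.0148) had means of -0.218 and -0.00900 without Western female 2 and -0.0670 and 0.154 without the library labelled Control female 1, where the calls were lost. They were 0.698 and 0.672 without Control female 2 and 0.782 and 0.836 without Western female 1, and the fat cell mean was 1.420 and 2.315. Cdh5, an endothelial cadherin, was at least 1.56-fold higher (6 arrays; 0.25 with normexp). B and plasma cell genes rose by 0.3 (adjusted p = 0.0148) and lost the call without the library labelled Control female 1 (0.0470) or Western female 1 (-0.123), with 0.552 without Control female 2 and 0.722 without Western female 2.

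Xenobiotic metabolism (0.0940, adjusted p = 0.0194), the Nrf2 list (0.0970, adjusted p = 0.0223), class I genes (0.0860, adjusted p = 0.0148), interferon response (0.00700, adjusted p = 0.0433), Wnt and stem cell genes (0.0840, adjusted p = 0.0148) and the PI3K, Akt and Foxo list (0.0660, adjusted p = 0.0148; 0.615 with an estimated correlation) were also called higher, relative to the other genes, whose median was -0.109. Without Control female 2 their means were -0.245, 0.00100, 0.162, 0.359, 0.242 and 0.150, and each call but that of interferon was lost. Without the library labelled Control female 1 the means of the last 4 were 0.0110, -0.335, -0.101 and -0.0180, and their calls were lost. Western female 2 ended the calls of xenobiotic metabolism (0.0160), Nrf2 (0.0770) and Wnt (-0.0200), and Western female 1 those of class I (-0.0250), interferon (-0.113) and PI3K (0.0980). The interferon call was also lost without Control male 1 or Control male 2, with the mean still 0.00700. Without the library labelled Control female 1, xenobiotic metabolism had 0.427 and Nrf2 0.194. Without Western female 1, xenobiotic metabolism had 0.171 and Wnt 0.239, without Western female 2, class I had 0.198, interferon 0.127 and PI3K 0.0340, and without Western male 1 interferon had 0.0470. The sex chromosome list fell by 3.81 (3 members, 1 past adjusted over the list alone, adjusted p = 0.0148), and by 0.897 without the library labelled Control female 1, where the call was lost, as it was without Western female 1 (-4.065), with -6.724 without Control female 2. Female values blocked by day equal those without it, since each day held 1 array of each diet. Within slide 1 the means were -0.0760 for fatty acid oxidation, -0.323 for xenobiotic metabolism, -0.0380 for Nrf2, 0.273 for class I, 0.468 for interferon, 0.114 for Wnt, 0.118 for PI3K, 0.975 for B and plasma cells, 0.132 for fibroblasts, 0.25 for endothelium, -0.0260 for fat cells and -6.470 for the sex chromosome list. Within slide 3 they were 0.503, 0.510, 0.233, -0.1, -0.455, 0.0540, 0.0140, -0.375, 0.432, 0.577, 1.765 and -1.151.

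The difference of the diet effect between the sexes was tested directly, as females minus males. Macrophage and dendritic cell genes were higher in this difference (mean 0.571, 24 of 29 members higher), and oxidative phosphorylation genes lower (-0.390, 74 of 76 lower), with adjusted p = 0.617 and 0.996 with an estimated correlation. Among genes well above background on all 8 arrays, Krt14 had a difference of -3.24 ± 0.40 SE (adjusted p = 0.593; -2.03 with normexp), and Klf2, a transcription factor of lymphocytes and endothelium, one of 2.34 ± 0.55 SE. Pdk4 had a difference of -0.73 ± 0.98 SE (adjusted p = 1.00; -0.14 with normexp). By limma, 0 genes passed (smallest adjusted p = 0.468), and 346 had an unadjusted p under 0.05 (98 higher, 248 lower). Without the library labelled Control female 1, 2 genes passed, the keratin gene Krt6a and Gm5476 (adjusted p = 0.0472 each, well above background on 3 arrays). Without Control female 2, 1 did, Ddx3y (adjusted p = 0.0365, 5 arrays).

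Of other genes with a small p here, Slc1a3 had 2.57 ± 0.52 SE, Cd40, a receptor of antigen-presenting cells, 1.35 ± 0.32 SE, Cd69, a lymphocyte activation marker, 1.85 ± 0.53 SE and Cmah, a sialic acid hydroxylase, 2.17 ± 0.63 SE (adjusted p = 1.00 each). Spats1, D6Ertd527e and Kng2 had -3.08, -2.93 and -3.20, and Cacnb4, a calcium channel subunit, -4.90 (adjusted p = 0.593 each). Apart from Cd40, these genes were well above background on 2 to 5 arrays, and with normexp Slc1a3 had 0.42, Cd40 0.47, Cd69 0.29, Cmah 0.44, Spats1 -0.39, D6Ertd527e -0.39, Kng2 -0.56 and Cacnb4 -0.80.

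Camera called 12 lists for this difference, 10 higher and 2 lower, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.617 and 0.890). Of these, 3 were kept whichever library was left out, and the calls lost numbered 5 without Control male 1, 2 without Control male 2, 5 without the library labelled Control female 1, 1 without Control female 2, 1 without Western male 1, 2 without Western male 2, 3 without Western female 1 and 3 without Western female 2. Macrophage genes had camera adjusted p = 7.26e-13. Their mean was 0.349 without Western female 2, 0.452 blocked by day and 0.427 within slide 1. Ly86 had 1.20 ± 0.38 SE and the growth factor receptor gene Csf1r 0.96 ± 0.36 SE. Oxidative phosphorylation had adjusted p = 6.41e-09. Its mean was -0.239 without Western male 2, -0.592 without Western female 1, -0.188 without Western female 2, -0.339 blocked by day and -0.0680 within slide 1. Ndufa11 and Cox6b1, subunits of complexes I and IV, had -0.79 ± 0.41 SE and -0.62 ± 0.34 SE. Erythrocyte genes were higher by 1.352 (5 of 7 members higher, adjusted p = 2.66e-06, 0.617 with an estimated correlation), with 2.095 without Western male 1, 0.609 without Western male 2, 1.199 blocked by day and 0.465 within slide 1. Hbb-bt had 2.35 ± 0.91 SE.

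B and plasma cell genes were higher by 0.546 (14 of 20 higher, adjusted p = 0.000238, 0.803 with an estimated correlation). Jchain and Mzb1, which serve antibody assembly, had 1.67 ± 0.66 SE and 1.49 ± 0.60 SE. The call was lost without Western male 2 (0.0960) or Western female 1 (0.123), and the mean was 0.294 without the library labelled Control female 1, 0.996 without Western male 1, 0.969 without Western female 2, 0.637 blocked by day and 0.874 within slide 1. Immediate early genes were higher by 0.313 (16 of 23 higher, adjusted p = 0.000780, 0.617 with an estimated correlation). That call was lost without Control male 2 (0.235) or the library labelled Control female 1 (0.0850), and the mean was 0.542 without Control female 2, 0.188 blocked by day and 0.424 within slide 1. T cell genes had a mean of 0.133 and a median of -0.0480 (adjusted p = 0.0177, 0.996 with an estimated correlation), and Paneth cell genes 0.213 (adjusted p = 0.0256, 0.996 with an estimated correlation). Blocked by day, both calls were lost (0.0740, adjusted p = 0.0570, and 0.174, adjusted p = 0.0518), and proliferation was called (0.124, adjusted p = 0.0261, 0.967 with an estimated correlation; -0.336 within slide 1). The T cell call was also lost without Control male 2 (-0.0200), the library labelled Control female 1 (-0.0950), Western male 2 (-0.190) or Western female 1 (-0.0390), and the Paneth call without Control male 1 (0.0610), Control female 2 (0.164), Western male 1 (0.0220) or Western female 2 (-0.105). Otherwise the T cell mean reached 0.321 without Control male 1, 0.288 without Control female 2, 0.437 without Western male 1 and 0.305 without Western female 2, and the Paneth mean 0.365 without Control male 2, 0.403 without Western male 2 and 0.530 without Western female 1. Within slide 1 they were 0.0230 and 0.189.

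Lists of other tissues moved with Control male 1 and Western female 2. Smooth muscle genes were higher by 1.615 (17 of 17 higher, adjusted p = 2.66e-06), fibroblast genes by 1.050 (24 of 30 higher, adjusted p = 1.20e-07), endothelial genes by 0.682 (9 of 13 higher, adjusted p = 0.000457) and fat cell genes by 1.348 (14 of 16 higher, adjusted p = 0.000602). With an estimated correlation adjusted p was 0.803 for each of these 4. Without Control male 1 the means were -0.198, -0.00200, 0.133 and 0.657, and the first 3 calls were lost. Without Western female 2 those of endothelium and fat cells were 0.260 and -0.0980, and without the library labelled Control female 1 they were 0.423 and 0.797, where these calls were lost. Without Control male 2 the 4 means were 3.473, 2.146, 1.231 and 2.039. Fibroblasts had 0.700 without the library labelled Control female 1, 1.595 without Western male 1, 0.601 without Western male 2 and 0.550 without Western female 2, and without Western female 1 endothelium had 1.105 and fat cells 2.794. The contractile genes Acta2 and Cnn1 had 3.04 ± 2.31 SE and 2.95 ± 2.33 SE, the collagen gene Col14a1 3.19 ± 1.13 SE (1.82 with normexp), the growth factor receptor gene Flt1 1.61 ± 0.64 SE (1.05 with normexp) and Fabp4 3.78 ± 2.51 SE. Blocked by day, the means were 2.116, 1.132, 0.638 and 0.913, and within slide 1 2.891, 1.546, 0.899 and 0.816. The sex chromosome list had -4.201 (1 of 3 members past adjusted over the list alone, adjusted p = 0.00499, 0.803 with an estimated correlation), -1.287 without the library labelled Control female 1, -4.256 without Control male 1 and -4.455 without Western female 1, where the call was lost, -7.115 without Control female 2, -3.126 blocked by day and -6.671 within slide 1.

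The second comparison in the design text set males against females, and values are female minus male. Class II antigen presentation genes were lower in females (mean -0.366, 7 of 11 members lower, camera adjusted p = 0.000233, 0.543 with an estimated correlation). H2-Aa was 2.70-fold lower (log2 -1.43 ± 0.35 SE), H2-DMb1 2.11-fold lower (log2 -1.08 ± 0.26 SE), H2-DMa 1.77-fold lower (log2 -0.83 ± 0.21 SE) and Cd74, the invariant chain, 1.96-fold lower (log2 -0.97 ± 0.28 SE, n = 4 arrays per sex). The acute phase genes Saa1 and Saa2 were 6.25-fold (log2 -2.64 ± 0.73 SE) and 7.38-fold (log2 -2.88 ± 0.74 SE) lower, and the protease gene Ctse 4.50-fold lower (log2 -2.17 ± 0.37 SE, adjusted p = 0.745, 6 arrays well above background). By limma, 0 genes passed (smallest adjusted p = 0.571), and 821 had an unadjusted p under 0.05 (567 higher, 254 lower). Adjusted p was 0.906 unless given. Without the library labelled Control female 1, 3 genes passed, the Y-linked Ddx3y (at least 22.2-fold lower, adjusted p = 0.00251), Eif2s3y (at least 167-fold, adjusted p = 0.0238) and Uty (at least 4.72-fold, adjusted p = 0.0238). With all arrays, of which 5 measured them, they had -4.73 ± 1.32 SE, -6.47 ± 1.79 SE and -2.61 ± 0.52 SE, and -1.80, -3.67 and -0.58 with normexp.

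Other genes with a small p were Ak4, an adenylate kinase, 5.75-fold lower in females (log2 -2.52 ± 0.45 SE, adjusted p = 0.745, 6 arrays), P4ha2, a collagen prolyl hydroxylase, 1.75-fold lower (log2 -0.80 ± 0.16 SE) and Gp9, a platelet glycoprotein, at least 1.74-fold lower (2 arrays). The ion channel gene Trpv1 was at least 1.74-fold higher (adjusted p = 0.571, 2 arrays), and Spats1, D6Ertd527e, Kng2 and Foxj1 differed by 1.63, 1.56, 1.70 and 1.70 (adjusted p = 0.571 each), all measured on the Control female arrays only. That bound sets no minimum sex effect. With normexp Ctse had -0.49, Ak4 -0.91, P4ha2 -0.40, Gp9 -0.14, Trpv1 0.50, Spats1 0.44, D6Ertd527e 0.38, Kng2 0.45 and Foxj1 0.40. Pdk4 differed by 0.87 ± 0.49 SE (0.57 with normexp).

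Camera called 24 lists for sex, 3 higher and 21 lower in females, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.543 and 0.393). By exact permutation the 24 had p from 0.0571 (class II and goblet cells) to 0.629 (macrophages), adjusted 0.670 to 0.728. The TCA cycle list, which was not called, had 0.0286 by that test (mean 0.157, adjusted 0.670). Without Control male 2, 14 lists were called. Of the 24, 5 were kept whichever library was left out. Class II genes had a median of -0.622 (6 past adjusted over the list alone). Their mean was -0.240 without Western male 1, -0.372 blocked by day, -0.484 within slide 1 and -0.393 within slide 3, where controls alone could be compared. H2-Aa differed by -1.47 blocked by day, -1.53 within slide 1 and -2.25 within slide 3. Interferon response genes fell by 0.318 (28 of 40 lower, adjusted p = 4.17e-06, 0.549 with an estimated correlation), with the chemokine gene Cxcl9 2.36-fold lower (log2 -1.24 ± 0.29 SE; -0.69 with normexp) and the guanylate-binding protein gene Gbp2 2.89-fold lower (log2 -1.53 ± 0.45 SE). That mean was -0.147 without the library labelled Control female 1, -0.496 without Control female 2, -0.348 blocked by day, -0.567 within slide 1 and 0.211 within slide 3. Erythrocyte genes fell by 0.880 (7 of 7 lower, adjusted p = 1.01e-05, 0.543 with an estimated correlation), with Hba-a2 at -0.96 ± 0.33 SE and the haem synthesis gene Alas2 at -1.43 ± 0.49 SE (-0.74 with normexp). Their mean was -0.509 without Western male 1, -0.957 blocked by day, -1.142 within slide 1 and -1.738 within slide 3, and without both Control female libraries it was -0.204 and the call was lost (adjusted p = 0.452). Adenoma-associated genes fell by 0.285 (17 of 27 lower, adjusted p = 0.000987, 0.543 with an estimated correlation), with -0.163 without Control male 1, -0.122 without Western male 1, -0.281 blocked by day, -0.609 within slide 1 and 0.208 within slide 3. The sex chromosome list fell by 4.605 (3 of 3 past adjusted over the list alone, adjusted p = 4.17e-06, 0.543 with an estimated correlation).

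The remaining 19 calls for sex were each lost without at least 1 library. Calls lost numbered 6 without Control male 1, 11 without Control male 2, 9 without the library labelled Control female 1, 6 without Control female 2, 5 without Western male 1, 3 without Western male 2, 6 without Western female 1 and 7 without Western female 2. Oxidative phosphorylation genes rose by 0.171 in females (72 of 76 higher, adjusted p = 0.000233, 0.685 with an estimated correlation), with Ndufa4 at 0.41 ± 0.17 SE and Atp5e at 0.30 ± 0.14 SE. They lost the call without the library labelled Control female 1 (0.175), Western male 1 (0.0950) or Western female 1 (0.0700). Fatty acid oxidation genes rose by 0.282 (35 of 45 higher, adjusted p = 0.0101, 0.668 with an estimated correlation), with the thioesterase gene Acot5 2.79-fold higher (log2 1.48 ± 0.43 SE; 0.18 with normexp, -0.21 without both Control female libraries). They lost the call without Control male 1 (0.227), the library labelled Control female 1 (0.167) or Western female 2 (0.233). Xenobiotic genes rose by 0.277 (29 of 33 higher, adjusted p = 0.0423, 0.685 with an estimated correlation). They lost the call without Control male 1 (0.322), Control male 2 (0.265), the library labelled Control female 1 (0.115), Western male 1 (0.109) or Western female 2 (0.238). Idh3a, a TCA cycle enzyme, had 0.52 ± 0.15 SE.

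Fibroblast genes fell by 0.522 in females (23 of 30 lower, adjusted p = 7.85e-06, 0.570 with an estimated correlation) and endothelial genes by 0.463 (9 of 13 lower, adjusted p = 0.000820, 0.549 with an estimated correlation), with Cdh5 3.67-fold lower (log2 -1.88 ± 0.53 SE, 6 arrays) and Flt1 2.13-fold lower (log2 -1.09 ± 0.32 SE), at -0.38 and -0.66 with normexp. Without Control male 1 these means were 0.00300 and -0.188 and the calls were lost. Granulocyte genes fell by 0.371 (14 of 20 lower, adjusted p = 0.000790, 0.549 with an estimated correlation; -0.0440 and lost without the library labelled Control female 1). Cytokine genes fell by 0.215 (median -0.0650, 17 lower and 15 higher, adjusted p = 0.0329, 0.624 with an estimated correlation), with Duoxa2, a maturation factor of an epithelial oxidase, 2.90-fold lower (log2 -1.54 ± 0.36 SE). They lost the call without Control male 1 (-0.0740), the library labelled Control female 1 (-0.0400), Western male 1 (-0.0410), Western female 1 (-0.163) or Western female 2 (-0.265). Class I (-0.125, adjusted p = 0.0152), T cell (-0.146, adjusted p = 0.00282) and macrophage genes (-0.0900, adjusted p = 0.0157) were called lower, with adjusted p = 0.549, 0.573 and 0.573 with an estimated correlation. The class I call was lost without Control male 2 (-0.0990), Control female 2 (-0.162) or Western female 2 (-0.0690). The T cell call was lost without Control male 2 (-0.0690), the library labelled Control female 1 (-0.0320), Western male 1 (0.0120) or Western female 2 (-0.0600). The macrophage call was lost without Control male 2 (-0.116), the library labelled Control female 1 (0.00200), Control female 2 (-0.147), Western male 1 (-0.0110) or Western female 1 (0.0210). Goblet cell genes fell by 0.204 (median -0.0440, adjusted p = 0.0113, 0.549 with an estimated correlation), with the mucin gene Muc2 at -0.54 ± 0.17 SE. They lost the call without Control male 2 (-0.219), Control female 2 (-0.224) or Western male 2 (-0.159). Of the antimicrobial lectin genes, Reg3g had -1.07 ± 0.26 SE and Reg3a 0.61 ± 0.19 SE.

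In females immediate early genes fell by 0.184 (adjusted p = 0.00231, 0.543 with an estimated correlation; lost without Control male 2, -0.145, or the library labelled Control female 1, -0.0700), Wnt genes by 0.156 (adjusted p = 0.00634, 0.549 with an estimated correlation; lost without Western female 1, -0.0780), and the PI3K, Akt and Foxo list by 0.122 and the Erk list by 0.103 (adjusted p = 0.00405 and 0.00943, 0.543 and 0.549 with an estimated correlation; both lost without Control male 2, -0.144 and -0.0830). Proliferation genes fell by 0.120 (28 of 34 lower, adjusted p = 0.00432, 0.685 with an estimated correlation). The call was lost without Control male 1 (0.0120), Control female 2 (0.00100) or Western female 1 (0.0390). Cholesterol synthesis fell by 0.108 (adjusted p = 0.0101, 0.573 with an estimated correlation) and lost the call without Control male 2 (-0.0670), Control female 2 (-0.0200) or Western female 1 (-0.0130). Glycolysis fell by 0.0940 (median -0.0220, adjusted p = 0.0213, 0.668 with an estimated correlation) and lost the call without Control male 2 (-0.00600), the library labelled Control female 1 (-0.00500), Western male 2 (-0.118) or Western female 2 (-0.0330). ER stress genes fell by 0.0790 (adjusted p = 0.0329, 0.570 with an estimated correlation) and lost the call without Control male 2 (-0.0660), Control female 2 (-0.0760), Western male 2 (-0.0180) or Western female 2 (-0.0120), and blocked by day (-0.0600, adjusted p = 0.0865), as did cytokine genes (-0.244, adjusted p = 0.0557). The other sex calls held with that block.

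Blocked by day, the sex means were 0.292 for fatty acid oxidation, 0.196 for oxidative phosphorylation, 0.324 for xenobiotic metabolism, -0.481 for fibroblasts, -0.485 for endothelium, -0.438 for granulocytes, -0.127 for class I, -0.176 for T cells, -0.150 for macrophages, -0.208 for goblet cells, -0.247 for immediate early genes, -0.190 for Wnt, -0.134 for PI3K, -0.134 for Erk, -0.0890 for proliferation, -0.124 for cholesterol synthesis, -0.133 for glycolysis and -4.067 for the sex chromosome list. Within slide 1 these lists had 0.494, 0.362, 0.607, -1.719, -1.162, -1.065, -0.119, -0.243, -0.400, -0.202, -0.279, -0.501, -0.281, -0.157, -0.341, -0.119, -0.0580 and -2.982. Within slide 3 they had 0.0220, 0.336, 0.172, 0.399, 0.00400, 0.868, -0.0430, -0.171, -0.138, -0.114, -0.191, 0.210, -0.0460, 0.0790, -0.129, -0.230, -0.0180 and -5.363. Cytokine genes had -0.794 and 0.377, and ER stress genes 0.0650 and 0.0190.

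Single libraries also moved sex means whose call held without them. Without Control male 1, glycolysis had -0.183, Wnt -0.0880, T cells -0.240 and granulocytes -0.188. Without Control male 2, proliferation had -0.253, cytokines -0.364, fibroblasts -1.070 and endothelium -0.737. Without the library labelled Control female 1, cholesterol synthesis had -0.196, Erk -0.0450, PI3K -0.0800, Wnt -0.0630, proliferation -0.242 and fibroblasts -0.347. Without Control female 2, glycolysis had -0.183, Erk -0.173, Wnt -0.262, xenobiotic metabolism 0.446, immediate early genes -0.298, granulocytes -0.756 and cytokines -0.394. Without Western male 1, cholesterol synthesis had -0.0630, PI3K -0.0430, Wnt -0.0480, proliferation -0.0710, ER stress -0.140, granulocytes -0.161 and fibroblasts -0.321. Without Western male 2, PI3K had -0.201, Wnt -0.264, xenobiotic metabolism 0.488, T cells -0.308, macrophages -0.170 and cytokines -0.425. Without Western female 1, glycolysis had -0.155, ER stress -0.153, T cells -0.232, fibroblasts -0.272 and endothelium -0.251. Without Western female 2, cholesterol synthesis had -0.203, oxidative phosphorylation 0.272, Wnt -0.276, proliferation -0.280 and macrophages -0.202.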

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

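Of the tests in this part, only those on olfactory and vomeronasal receptor probes and the counts of other splits were chosen before the result was seen. Of 56 groups of 4 arrays examined for an array far from the rest, 5 had one, and chance gives about 1 in 20.

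Among the female arrays, the library labelled Control female 1 stood far above the others in Ddx3y (-0.46), and Control female 2 stood far below the other control diet arrays in the same gene (-6.91). The mean of the Y-linked genes Ddx3y, Eif2s3y and Uty on the library labelled Control female 1 lay 0.21 above the mean of the male arrays (SD of these 0.25), which is consistent with a mislabelled sample. A swap with a library labelled male is argued against, since the lowest Ddx3y among these was -1.04. A pool of males with at least 1 female among 3 mice, or carry-over of male RNA that left that share of female RNA, would lie at -0.58 or lower, which the value of 0.21 exceeds by more than the spread. A mix-up with a sample outside the series and carry-over of male DNA stay open and were not tested, and no biological explanation was tested.

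Control female 2 stood apart among the female arrays with 29817 probes well above background and with the lowest 75th percentile (486.3). Of 1440 probes for olfactory and vomeronasal receptors, genes not known for expression in intestine, 50% were well above background there, against at most 12.6% on another array, so nonspecific signal on that array is a candidate explanation. RNA of another tissue is argued against, since receptor probes were newly detected 1.02 times as often as other probes (43.4% against 42.3%). The scaling is also argued against as the whole source, since the deviation of dim genes exceeded that of bright genes by 2.77 log2. No biological explanation was tested.

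The fatty acid oxidation list was higher on the Western diet (0.293). The enterocyte list (-0.11 ± 0.18 SE) cannot settle a larger share of enterocytes, since it holds Sis, itself lower on the Western diet. The Control female libraries are argued against as the whole source, since without both the mean in males was 0.36. Without Control male 1 and Western female 2, which had high smooth muscle or fat cell markers, the mean was 0.21 against 0.29, and a part of these tissues in it cannot be told apart from the loss of an array in 2 groups. An effect of diet, which the design names, stays open as a hypothesis and was not tested apart from these.

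Other splits of the 8 arrays into 2 groups of 4 did not exclude chance for the list counts. For diet, 27 of 35 splits gave as many lists as the real one (10 in a fit of 2 groups, highest other 24), and for sex 3 of 35 did (24, highest other 24). The real gene counts were 0 for diet and for sex, which any split reaches (35 of 35 for each, highest other 13), so these say nothing about chance. The split with 13 genes was that of sex with Western male 2 and Western female 2 exchanged, a structure of the samples whose cause was not tested.

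Western male 2 stood far above the other male arrays in the xenobiotic list mean (0.542). By camera 12 lists differed in diet effect (females minus males), each lost with an estimated correlation: oxidative phosphorylation (-0.390), Paneth cells (0.213), immediate early genes (0.313), T cells (0.133), B and plasma cells (0.546), macrophages (0.571), fibroblasts (1.050), smooth muscle (1.615), endothelium (0.682), fat cells (1.348), erythrocytes (1.352) and the sex chromosome list (-4.201).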

How the results depend on the processing

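The alternatives that leave out both Control female libraries, or Control male 1 with Western female 2, or that keep the genes chosen on 8 arrays, as well as scan day as a block and the normexp correction, were chosen after seeing the data. Normexp was run on median signals with local background, since mean signals are not in the files used here. Signals near background leave only bounds for dim genes. With normexp, 9 of 45 values of named genes moved by more than 1.5 times for diet, 10 of 21 in males, 10 of 19 in females, 12 of 23 for the difference between the sexes and 18 of 33 for sex. Over the settings with a test such values passed the threshold in 17 cases and turned in 7, and since none passed at first, the 3359 others say little. In these settings the called diet lists kept direction and call in 171 cases, lost the call in 42 and turned in 3, Pdk4 for diet lay between 2.12 and 3.6 (adjusted p 0.0847 to 1.00) and the fatty acid oxidation list between 0.131 and 0.408 (adjusted p 1.67e-11 to 0.988). The cause was not tested except where fewer arrays or genes give it.

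Called diet lists numbered 13 with normexp, 16 with no filter on dim probes, 15 within slide 1 and 17 without both Control female libraries, against 8. With an estimated correlation or by fry, 0 lists were called for diet, the difference between the sexes or sex, against 8, 12 and 24. Without both Control female libraries sex lists numbered 14. Members of the fatty acid oxidation list past the threshold adjusted over the list alone were 1 with quantile normalization, no filter, every probe, array weights, the additive model or slide 1 alone, and 0 with scan day as a block, without both Control female libraries, without Control male 1 and Western female 2, or without Control female 2, against 2. Interferon members were 1 with quantile normalization and 4 within slide 1, against 0. Granulocyte and mast cell members were 2 with quantile normalization, 1 with array weights, 4 within slide 1 and 1 without either or both Control female libraries, against 0. Erythrocyte members were 0 without both Control female libraries, without the library labelled Control female 1, or without Control male 1 and Western female 2, against 5.

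With genes kept as chosen on 8 arrays and the library labelled Control female 1 left out, 393 genes passed in females, 2 for the difference and 3 for sex, and without Control female 2, 2 passed in females; 3 passed for sex without both. At an unadjusted p under 0.05 with a 2-fold difference, 366 genes passed for diet, 176 in males, 724 in females, 312 for the difference and 337 for sex, and at an adjusted p under 0.10, 11 passed in females.

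Directions turned for Clec10a (diet, -0.03 with normexp), Acot5 (sex, -0.21 without both Control female libraries), Cfd (females, -0.33), Cnn1 (-0.27) and Acta2 (-0.26, both for the difference) without Control male 1 and Western female 2, the xenobiotic list (-0.127 within slide 1) and the interferon list (-0.0200 without the library labelled Control female 1, with either choice of genes). Within slide 3, where no test could be made, Pdk4 had 3.85 and the fatty acid oxidation list 0.503, and class I (-0.1), interferon (-0.455) and granulocyte genes (-0.467) turned for diet, as did Mcpt1, Mcpt4, Rsad2, Atp5g3 and Reg3a. With 1 array left out in turn, the lone array of a group is assumed to vary like the others. Genes passing then ranged from 0 to 1 for diet, 0 to 2 in females, 0 to 2 for the difference and 0 to 3 for sex, called lists from 7 to 14, 8 to 18 and 14 to 27 for diet, the difference and sex, and members past the threshold from 0 to 3 for fatty acid oxidation, 0 to 1 for Nrf2, 0 to 1 for granulocytes and 0 to 5 for erythrocytes. Myh11 in males ranged from -6.08 to 0.00, Cfd in females from -0.33 to 7.29 and the interferon list from -0.0200 to 0.308.

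With replicate number as a block, 0 genes passed in each comparison, 9 lists were called for diet, 12 for the difference and 22 for sex, and fatty acid oxidation members were 0. Arrays with the same number correlated between groups by -0.12 to 0.35, with 0.35 and 0.18 between the diets within males and within females. Not every pair was above 0.1, so the numbers were not taken to pair the samples. Arrays numbered 1 all lay on slide 1, so this block also follows that slide.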
